A study of Homo sapiens with 6 samples.

How the data were processed

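Methylated RNA immunoprecipitation libraries of U-251 MG glioblastoma cells were made from fragmented total RNA with a stranded kit and sequenced in pairs, per the labels' protocols. The labels give 6 libraries, an immunoprecipitated and an input library for each of shNC, shTRA2A and shMETTL3, so 1 library pair per condition. The submitters' processing notes name HISAT2 2.2.1, SAMtools, featureCounts 2.0.1 and the build GRCh38. The peak caller, its thresholds and the read depth per library are not given in the sources used here.

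The deposited files are peak lists in 12-column BED form without a header. Column 5 of each is a score that the authors' peak caller gave to each peak, whose scale and log base are not stated per the labels or in the lists. A larger score was taken as a stronger peak, and the score was used to describe, rank and filter peaks within a list. It ran from 6.04 to 392 in shNC (median 12.4), from 3.39 to 54.5 in shTRA2A (median 8.00) and from 3.33 to 151 in shMETTL3 (median 8.40), so neither sizes nor thresholds are comparable between lists. Of 4 lists, 3 match a condition in the labels. The name of the other matches no label and its contents equal the shTRA2A list byte for byte, so it entered no comparison. All shNC peaks and all but 1 peak in each knockdown list are single blocks. Widths are multiples of 25 nt except for 19.4% of shNC, 32.6% of shTRA2A and 29.7% of shMETTL3 peaks, whose median widths are 2041, 2421 and 2052 nt. A peak is called regular here if it is 1 block, a multiple of 25 nt wide and at most 1000 nt wide. That rule was set after the widths were seen. Of the peaks, 7356, 1822 and 3769 are regular.

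Peaks were compared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. A peak was found in another list if it shared at least 1 base on the same strand with a peak there. Strand is as the lists give it, and whether it was handled alike in all lists is not given in the sources used here. The overlap code was tested on simulated data and gave the same answer as bedtools 2.31.1 for every control peak (0 differed). Shares carry exact Clopper-Pearson 95% intervals. The intervals treat each peak or gene as independent and cover counting error alone. Amplified reads are not independent molecules, and peaks of the same gene or of an opposite-strand pair may not be independent either. The intervals may therefore be too narrow. Coordinates are those of the lists turned to count from 1, on GRCh38.

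Genes came from an NCBI RefSeq table of gene bodies (GRCh38.p14) with 20046 coding and 18303 long non-coding genes, without strand or exons. A peak was given the coding gene whose body it touches. Where it touches several, it was given the one that holds the whole peak and lies inside all others, and without a coding gene the same was done among long non-coding genes. This nesting step was chosen after it was seen that IFIT1, IFIT2 and IFIT3 lie inside the body of LIPA. Of the peaks, 94.9%, 94.6% and 94.7% were assigned in shNC, shTRA2A and shMETTL3. The direction of a gene body was taken from the strand of the peak. In coding genes with 3 or more peaks, 480 of 10929 peaks, 4.39%, were on the strand with fewer peaks.

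The comparisons, the overlap rule, the gene lists and the genes to name were fixed before the data were examined. TRA2A, METTL3, IFIT1, IFIT2, IFIT3, IFIT5 and EGFR are named whatever their values. Per knockdown the text names the 10 genes with the strongest control peak among genes without a knockdown peak, the 8 whose strongest control peak overlaps a knockdown peak, and the 5 with the strongest knockdown peak among genes without a control peak. Ties were broken by width and symbol, and genes known only by a locus number were passed over. An exact score was shared with another peak of the list by 2886 of 9206 shNC, 1778 of 2736 shTRA2A and 2149 of 5433 shMETTL3 peaks. Ranks and score deciles therefore depend in part on how ties were broken. Up to 4 members were taken per gene list, the 2 with the best control peaks among those found and among those not found, and other members named in the text were chosen after their values were seen. There are 17 lists: the IFIT family, interferon-stimulated genes, RNA methyltransferases, m6A demethylases and readers, EGFR signalling, endocytosis and recycling, splicing factors, cell cycle, glioma markers, extracellular matrix, m6A example transcripts, chromatin regulators, energy metabolism, markers of other brain and blood cells, ribosomal proteins, ZNF genes and histones. A listed gene counts as found if any peak was assigned to it in the knockdown list. Its list's count is placed as a percentile among 10000 random sets of control peak genes matched on quintiles of control peak length, with ties counted by their middle. This describes these lists and is no test between conditions.

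Alternatives for the overlap rule, the score threshold, merging of peaks within 100 nt, strand and gene assignment were run, and their values are given in the closing section. DRACH motif shares and transcript regions had been planned. They need a genome sequence and exons, which were not used here, and the position along the gene body was computed in their place, as an addition made after the files were seen.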

Results

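N6-methyladenosine (m6A) was mapped in U-251 MG, a human glioblastoma cell line, by methylated RNA immunoprecipitation sequencing, in which fragmented RNA is pulled down with an antibody against m6A and sequenced beside the input RNA. Cells carrying a control short hairpin RNA (shNC) were set against cells with a hairpin against TRA2A, an SR-like RNA-binding protein that regulates splicing, and against cells with a hairpin against METTL3, the catalytic subunit of the m6A writer complex. Each of the 3 conditions had 1 immunoprecipitated and 1 input library, so 6 libraries in all, and each condition is represented here by 1 peak list. No difference below therefore has a replicate check, and no test between conditions was made. Read depth per library is not given in the sources used here. Intervals are exact Clopper-Pearson 95% intervals and cover counting error alone.

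The control list held 9206 peaks in 4148 genes, the shMETTL3 list 5433 peaks in 3233 genes and the shTRA2A list 2736 peaks in 1830 genes. In the control the genes with the most peaks were CENPF, a kinetochore protein, with 26 peaks, DST, a cytoskeletal linker, with 25, VCAN, the matrix proteoglycan versican, with 24, and FAT1, a large cadherin, with 21. In the shTRA2A list these genes had 2, 6, 7 and 8 peaks, and in the shMETTL3 list 12, 8, 5 and 9. These genes were picked by their control peaks, so lower counts in the other lists come in part from that choice. Some of the genes with the most shMETTL3 peaks went the other way there. ZC3H13, itself a subunit of the m6A writer complex, had 9 control, 8 shTRA2A and 13 shMETTL3 peaks, ARSJ had 4, 2 and 9, and MTCL1 had 2, 2 and 9. Median peak width was 125 nt in the control and 100 nt in both knockdown lists. The lists covered 6295831, 2965984 and 5131234 nt for shNC, shTRA2A and shMETTL3. These lengths count the full spans of the wide peaks whose width is not a multiple of 25 nt, which may cross introns. They are therefore no measure of methylated sequence.

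Peak lists carry no transcript levels, so they do not measure how far either hairpin reduced its target. METTL3 (14:21498138-21511340, GRCh38) had no peak in any list. TRA2A (7:23504780-23531981) had no control and no shMETTL3 peak and 1 shTRA2A peak of 50 nt at 7:23531618-23531667, with a score of 7.57.

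The comparison of shTRA2A with shNC addresses whether m6A peaks of the control remain when TRA2A is targeted. Of the 9206 control peaks, 882 overlapped an shTRA2A peak, 9.58% (8.99 to 10.2%). Of the 2736 best control peaks, as many as the shTRA2A list holds, 22.1% did. Among the strongest control peaks without an shTRA2A peak in the gene were those of FAM111A, a protease that restricts viral replication (11:59149149-59153068, score 179), IFIT5 (score 162), N4BP1, an interferon-induced ribonuclease (16:48561194-48562218, score 121), NCOA6, a nuclear receptor coactivator (score 119), and N4BP2L2 (13:32535950-32536949, score 118). Strong control peaks found again lay in EIF5B, a translation initiation factor (2:99360317-99363766, score 199), HMGN5, a nucleosome-binding protein (X:81114624-81115148, score 199), RND3 (2:150469645-150471807, score 143), and ZNF146, a zinc finger protein (19:36237279-36238153, score 136).

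By gene, 1188 of the 4148 control peak genes also had an shTRA2A peak, 28.6% (27.3 to 30.0%). The other strongest control peaks in genes without an shTRA2A peak were all 75 nt wide. They lay in PCDHB5, a protocadherin (5:141137108-141137182, score 391), TXLNB (score 135), PIGB, a mannosyltransferase of GPI anchor synthesis (score 116), PELO, a ribosome rescue factor (score 110.2), and ITGA1, an integrin subunit (score 109). Those of PCDHB5, TXLNB, PIGB and ITGA1 were the only peaks assigned to their genes in any list, so their strand could not be checked. The NCOA6 peak was on the strand opposite to all 8 other peaks of that gene. When only peaks of regular width above 75 nt were taken, a choice made after the widths were seen, the leading genes without an shTRA2A peak were NCOA6, N4BP2L2, FILIP1L (score 97.4), DIO2, the activating thyroid hormone deiodinase (score 94.7, 9 control peaks), and TMCC1 (score 89.9). ANKDD1A, OGFRL1, RASSF8 and ZFPM2 completed the 8 strongest control peaks found again, each with a control peak of 6016 to 9826 nt, and the peaks of OGFRL1 and ZFPM2 were on the strand opposite to most other peaks of the gene.

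Most shTRA2A peaks were not on a control peak, though most shTRA2A peak genes had one. Of the 2736 shTRA2A peaks, 926 overlapped a control peak, 33.8% (32.1 to 35.7%), and 1188 of the 1830 shTRA2A peak genes had a control peak, 64.9% (62.7 to 67.1%). In the top decile of the shTRA2A list by score, 60.4% of 273 peaks were on a control peak, and in the lowest decile 32.6%. The strongest shTRA2A peaks in genes without a control peak were in COPG2, a coatomer subunit (7:130546807-130546856, score 29.4), TAF15, an RNA-binding protein (17:35844923-35846939, score 23.2), HNRNPA2B1, an RNA-binding protein described as an m6A reader (7:26193274-26193599, score 17.8), PLEKHA4 (score 17.7) and CSF1, the macrophage growth factor (1:109929130-109929454, score 17.3). Regular shTRA2A peaks in coding genes overlapped a regular control peak in 35.4% of cases. Over 100 random placements within the same gene bodies, introns included, the mean was 2.01% and the highest value 3.04%. The placements kept neither exons nor the concentration of peaks towards the 3′ end. The contrast therefore cannot separate shared sites from shared position along genes.

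The share of control peaks found in the shTRA2A list climbed with the control score, from 0.923% (0.539 to 1.47%) in the lowest quintile to 28.2% (26.2 to 30.4%) in the highest. For shMETTL3 it went from 2.71% (2.02 to 3.56%) to 44.2% (41.9 to 46.5%). With control peaks ranked by width instead, the lowest and highest quintiles gave 3.37% and 16.0% for shTRA2A and 6.73% and 25.3% for shMETTL3, whose share was highest, 31.8% (29.7 to 34.0%), in the quintile below the widest. When the shMETTL3 list was limited to its best peaks, as many as the shTRA2A list holds, it contained 11.4% of the control peaks in place of 17.9%, a limit chosen after the data were seen.

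**Figure D1:**
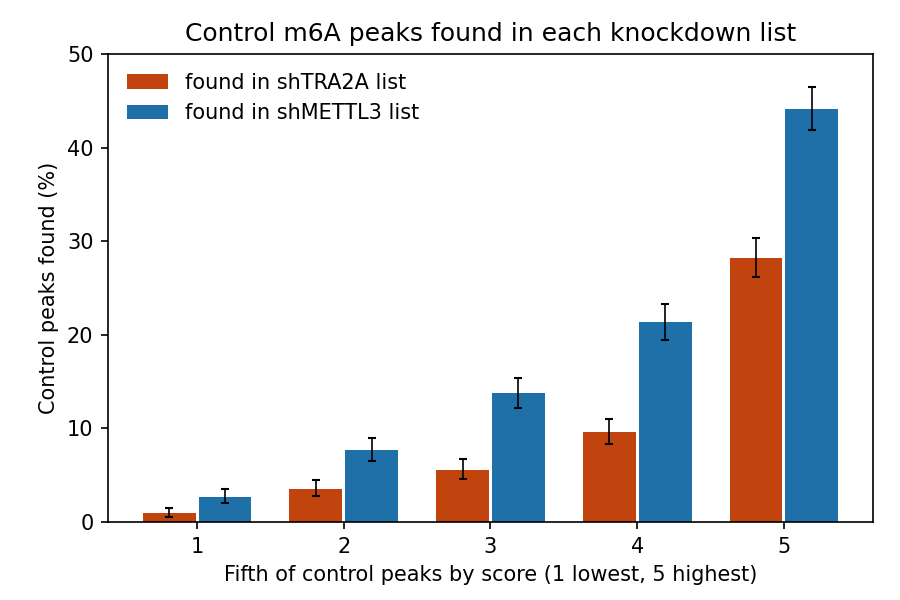
Share of control (shNC) m6A peaks, in percent, that overlap a peak of the shTRA2A list (orange) or the shMETTL3 list (blue), by quintile of the control peaks by the authors' score. Bars are shares of about 1841 peaks each and error bars exact 95% intervals for counting error; the share is highest in the top quintile, at 28.2% and 44.2%.

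The IFIT genes encode interferon-induced proteins with tetratricopeptide repeats, which bind viral RNA, and the series title names them. Of the 5 family members 3 had control peaks, 1 of these had an shTRA2A peak (50.7th percentile of random sets, 26.5th when matched on score, and 0 in the better-scoring 50% of each list), and none of their 8 control peaks overlapped an shTRA2A peak. IFIT5 (10:89414568-89420997) had 1 control peak at 10:89417294-89418468, 1175 nt wide, and no shTRA2A peak. That control peak had a score of 162, rank 9 in the list, tied with a peak of OGFRL1. IFIT2 (10:89302046-89309271) had 5 control peaks between positions 89306045 and 89307819, with scores of 25.9 to 39.9, and no shTRA2A peak. IFIT1 (10:89392623-89406487) had control peaks at 89403299-89403398 (score 44.0) and 89403699-89403748 (score 25.1) and 1 shTRA2A peak between them, at 89403424-89403473 (score 7.72). The midpoints of that shTRA2A peak and the first IFIT1 control peak lie within 100 nt, so the midpoint rule would count the control peak as found. The random sets below use the rule of at least 1 shared base alone. IFIT3 (10:89327997-89340968) had neither a control nor an shTRA2A peak. In 4.61% of 10000 random sets of 8 control peaks of matched score, no peak overlapped an shTRA2A peak, and the mean was 2.40. Because 5 of the 8 peaks lie in IFIT2, sets of 3 genes were also drawn, matched on the best control score, and in 8.22% of these no gene had a control peak overlapped. Neither draw was matched on width, and the IFIT1 and IFIT2 control peaks were 50 to 200 nt wide. Of the 100 best control peaks, 4 of 21 that were 100 nt or narrower were found in shTRA2A, against 48 of 79 wider ones. The 4.61% and 8.22% may therefore be too low and the mean of 2.40 too high.

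In the shMETTL3 list all 3 of these genes had a peak (93.1st percentile, 78.6th when matched on score), 1 of them in the better-scoring 50% of each list, and 2 of the 8 control peaks were overlapped. Both shMETTL3 peaks of IFIT5, at 89417344-89417418 and 89418344-89418468, lay inside its control peak, with scores of 14.9 and 6.65. They lay near its ends, so the rule of midpoints within 100 nt would not count that control peak as found. IFIT2 had 2 shMETTL3 peaks, 1 of them on a control peak, and IFIT1 had 3 that missed both control peaks. IFIT3 had 1 shMETTL3 peak at 89338960-89339084 (score 9.66). Of the matched random sets of peaks, 19.8% had 2 or fewer overlapped, and of the sets of genes, 67.6%. These sets too were not matched on width.

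EGFR, the receptor tyrosine kinase named in the series title, had 6 control peaks between 7:55205264 and 7:55206413, with scores of 10.5 to 15.4. The last of them, at 55206239-55206413, was overlapped by the 1 shTRA2A peak (55206264-55206338, score 7.59) and by the 1 shMETTL3 peak (55206314-55206388, score 5.41). Of the EGFR pathway list, 6 of 23 genes with a control peak had an shTRA2A peak and 7 of 23 an shMETTL3 peak, at the 61.6th and 14.9th percentiles of random sets. By overlap with a control peak these counts were 3 and 4. In the better-scoring 50% of each list they were 1 and 3, though there the control list is cut too, so these are not out of 23. Members with a peak in both knockdown lists included JUN, a subunit of the AP-1 transcription factor, with 1 control, 2 shTRA2A and 3 shMETTL3 peaks. ERRFI1, a feedback inhibitor of EGFR, had 1 control peak (score 41.9) and SOS1, a Ras activator, had 4, and neither gene had a peak in the knockdown lists. PIK3R1, a regulatory subunit of PI3-kinase, had 6, 0 and 3 peaks in shNC, shTRA2A and shMETTL3.

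Interferon-stimulated genes with a control peak had an shTRA2A peak in 8 of 26 cases, 30.8% (14.3 to 51.8%), at the 67.4th percentile, or at the 22.2nd when sets were matched on the best score. SAMD9L and PARP14, both antiviral effectors, had 9 and 4 control peaks and 1 and 2 shTRA2A peaks. SAMD9 had 12 control peaks and no shTRA2A peak. XAF1, a proapoptotic interferon target, had 11 control peaks and none in either knockdown list. The XAF1 peaks were 6 on the plus and 5 on the minus strand. In shMETTL3, 14 of the 26 genes had a peak, 53.8% (33.4 to 73.4%), at the 83.5th percentile, or the 33.4th when matched on score, and SAMD9 had 6 peaks. Where a control peak had to be overlapped, 3 and 8 of the 26 genes remained. Of the 25 interferon-stimulated genes with an shMETTL3 peak, 11 had no control peak. Of all shMETTL3 peak genes, 1289 of 3233, 39.9%, had none either. Among the 11, GBP3 (score 13.9) and EIF2AK2, the double-stranded RNA-activated kinase PKR (score 12.2), were the strongest.

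The m6A machinery divided by gene. Of 9 writer complex and other RNA methyltransferase genes with a control peak, 4 had an shTRA2A peak and 6 an shMETTL3 peak, at the 72.8th and 76.5th percentiles. ZC3H13 and VIRMA, subunits of the writer complex, had peaks in all lists, VIRMA with 7, 1 and 5. WTAP, another subunit, had 5 control peaks and none in either knockdown, as had METTL16, a separate methyltransferase, with 2. Of 9 demethylase and reader genes, 2 had an shTRA2A peak, YTHDC1 and YTHDF2, and 6 an shMETTL3 peak, at the 37.0th and 88.0th percentiles. FTO, a demethylase, had 1 control peak (16:53826172-53826446, score 43.2) and none in the knockdown lists.

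Chromatin regulators with a control peak often had a peak in the knockdown lists. Of 39 with a control peak, 24 had an shTRA2A peak, 61.5% (44.6 to 76.6%), at the 100.0th percentile of random sets, and 31 an shMETTL3 peak, 79.5% (63.5 to 90.7%), at the 99.995th. EP300, a histone acetyltransferase, had 7, 1 and 1 peaks and KDM5A, a histone demethylase, 3, 1 and 1. CHD8, a chromatin remodeller, had 8, 0 and 2, and TET2, a 5-methylcytosine dioxygenase, 4, 0 and 1. Where a gene had to keep a control peak by overlap, 10 and 15 of the 39 did so. In the better-scoring 50% of each list the counts were 9 and 18, though there the control list is cut too, so these are not out of 39. Zinc finger genes named ZNF lay at the other end, with 46 of 231 found in shTRA2A, 19.9% (15.0 to 25.7%), at the 0.065th percentile, and 83 in shMETTL3, 35.9% (29.7 to 42.5%), at the 0.010th, or the 1.41st and 0.555th when matched on score. By overlap with a control peak the ZNF counts were 24 and 44, and in the better-scoring 50% of each list, control list included, 23 and 41. ZNF146 and ZNF638 were found in both lists, ZNF281 and ZNF800 in shMETTL3 alone.

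Extracellular matrix and adhesion genes were found in the shTRA2A list in 15 of 22 cases, 68.2% (45.1 to 86.1%), at the 99.985th percentile, and in shMETTL3 in 13, 59.1% (36.4 to 79.3%), at the 89.4th, or the 99.895th and 62.6th when matched on score. VCAN had 24, 7 and 5 peaks and ITGB8, an integrin subunit, 1, 2 and 1. ACTN1, an actin crosslinker, had 2, 0 and 0. With overlap required, 5 and 7 of the 22 genes remained. Over all listed genes the overlap rule gave 17.0% and 26.1% in place of 32.5% and 46.2%, and 20 of the 34 list counts moved by over 1.5 times. SR proteins and splicing factors, the group to which TRA2A belongs, were found in 12 of 23 cases in each list, 52.2% (30.6 to 73.2%), though not all the same genes. These counts lay at the 97.9th percentile for shTRA2A and the 54.5th for shMETTL3, or the 87.7th and 19.2nd when matched on score. With overlap required the splicing factor counts were 7 and 11, and with regular peaks alone 9 and 6. PNN and RBM25, both splicing-associated proteins, had 3 and 5 control, 3 and 2 shTRA2A, and 2 and 3 shMETTL3 peaks. SRPK1, a kinase of SR proteins, had 4 control peaks and none in the knockdown lists.

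Glioma stem, neural and mesenchymal markers were found in 11 of 23 cases in each list, though not all the same genes. These counts lay at the 95.4th percentile for shTRA2A and the 38.3rd for shMETTL3, or the 88.6th and 21.3rd when matched on score. SOX9, a glial transcription factor, had 1 peak in every list. MYC and ID2, both transcriptional regulators, had 1 control peak each (scores 32.3 and 37.2) and none in the knockdowns. MET, the hepatocyte growth factor receptor, had 3, 1 and 0. Cell cycle and replication genes were found in 6 and 9 of 17 cases, at the 61.7th and 54.7th percentiles, MKI67 with 17, 5 and 6 peaks and CENPE, a centromere motor, with 2, 0 and 0. Endocytosis and endosomal recycling genes were found in 7 and 8 of 18 cases, at the 74.7th and 31.2nd percentiles. USP8, an endosomal deubiquitinase of EGFR, had 3, 1 and 1 peaks and ARF6, a recycling GTPase, 1, 0 and 0. RAB8A had 8 control peaks and none in the knockdowns, and was picked out after its values were seen. Of 10 transcripts often used as m6A examples, 6 and 7 were found, at the 95.4th and 85.1st percentiles, among them EP300 and TUG1, with 16, 5 and 6 peaks. The best control peak of TUG1 was on the minus strand, as were 7 of its other peaks, and 19 were on the plus strand.

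**Figure D2:**
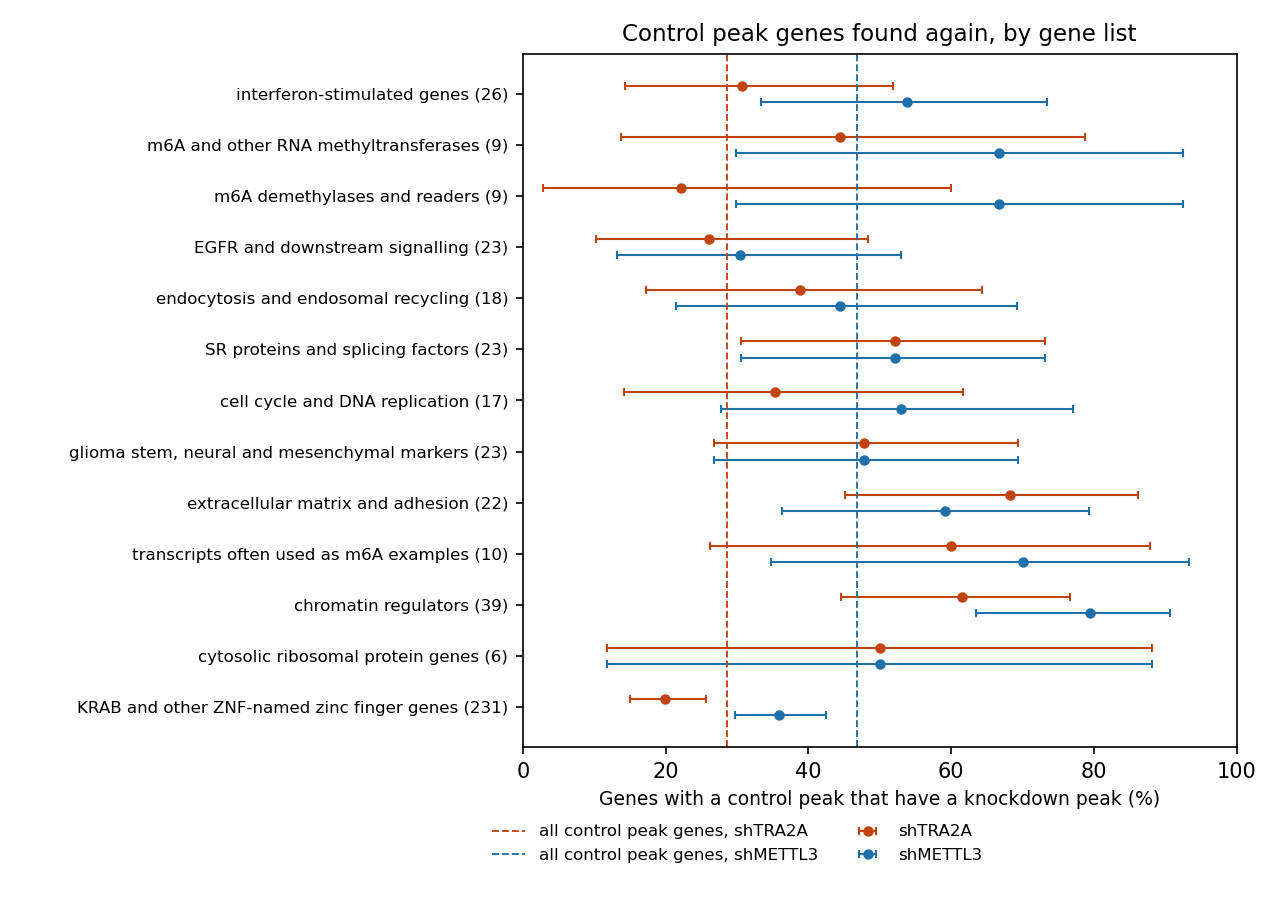
Share of genes with a control m6A peak, in percent, that also have a peak in the shTRA2A (orange) or shMETTL3 (blue) list, for the gene lists with at least 5 such genes (number in brackets). Points are shares, bars exact 95% intervals for counting error, and dashed lines the shares over all 4148 control peak genes, 28.6% and 46.9%; chromatin regulators lie to the right of the line of each list and zinc finger genes to its left.

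Genes with few control peaks gave little to compare. Of 6 ribosomal protein genes 3 were found in each knockdown list, at the 94.7th and 76.8th percentiles (86.3rd and 53.5th when matched on score), and of 4 histone genes 1 in each, at the 45.8th and 21.4th. Among 43 genes of oxidative phosphorylation and glycolysis only HK2, a hexokinase, had a control peak, and it was found in neither list (30.2nd and 19.2nd percentiles). Among 22 markers of other brain and blood cell types only SLC1A3, an astrocyte glutamate transporter, had a control peak, with 3, 0 and 2 peaks (36.1st and 75.5th percentiles).

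The comparison of shMETTL3 with shNC addresses which control peaks remain when the m6A writer itself is targeted. Of the 9206 control peaks, 1650 overlapped an shMETTL3 peak, 17.9% (17.1 to 18.7%), and 1944 of 4148 control peak genes had one, 46.9% (45.3 to 48.4%). Strong control peaks without an shMETTL3 peak in the gene lay in N4BP1 (score 121), POLR1F, a subunit of RNA polymerase I (7:19698361-19700204, score 106), C1GALT1C1, a chaperone of O-glycosylation (X:120626224-120627048, score 92.7), TMCC1 (3:129670343-129671042, score 89.9) and the long non-coding RNA LINC00342 (score 103). The narrow peaks of PCDHB5, TXLNB, PIGB and ZKSCAN7, a zinc finger gene (score 99.5), and the 9543 nt peak of ZFPM2 completed these 10. ZKSCAN7, like PCDHB5, TXLNB and PIGB, had no other assigned peak in any list, so the strand of these narrow peaks could not be checked. Found again were the peaks of FAM111A and IFIT5, both absent from shTRA2A, and those of ANKDD1A, EIF5B, HMGN5, RASSF8, RND3 and ZNF146.

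Among regular peaks above 75 nt, C1GALT1C1, TMCC1, MET (7:116797704-116798253, score 82.2), ENAH, an actin regulator (score 77.5), and CCDC82 (score 64.3) led the genes without an shMETTL3 peak. HMGN5, ZNF146, MAP3K4, a stress kinase (score 135), PPIG and PRPF38B, both linked to splicing, led those found again, and PPIG (score 125) and PRPF38B (score 125) were also found in shTRA2A. Of the 5433 shMETTL3 peaks, 1775 were on a control peak, 32.7% (31.4 to 33.9%), and 1944 of 3233 genes had a control peak, 60.1% (58.4 to 61.8%). The strongest shMETTL3 peaks in genes without a control peak were in TAF15 (17:35820271-35820320, score 99.6), ALG10, a glucosyltransferase of N-glycan synthesis (12:34024068-34025945, score 74.4), TXNDC5, a disulfide isomerase (6:7882842-7882891, score 57.3), CLASP1, a microtubule-binding protein (score 48.9), and NUDT4 (score 46.5). In the top decile of the shMETTL3 list 42.9% of 543 peaks were on a control peak and in the lowest decile 17.7%. Regular shMETTL3 peaks overlapped a regular control peak in 35.2% of cases, against 1.90% on average and 2.48% at most over random placements. These placements too ignored exons and the 3′ concentration of peaks, so the contrast has the same limit as for shTRA2A.

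Both knockdown lists were then set side by side. Of the 9206 control peaks 7135 were in neither, 77.5% (76.6 to 78.4%), 461 were in both, 421 in shTRA2A alone and 1189 in shMETTL3 alone. Independent lists would give 158 peaks in both, or 287 within quintiles of the control score, and 6832 or 6961 in neither. Part of the excess may come from the shared control list. By gene, 826 had a peak in all lists, against 557 for independent lists, and 1842 control peak genes had none in either knockdown, 44.4%, against 77.5% of peaks. EP300, ZC3H13, VCAN and EGFR were among the genes with a peak in every list, and WTAP, FTO, XAF1 and MYC among those with control peaks alone. Of the shTRA2A peaks that were on a control peak, 47.0% (43.7 to 50.3%) overlapped an shMETTL3 peak, and of those that were not, 11.9% (10.4 to 13.5%). The reverse shares for shMETTL3 peaks were 24.6% (22.6 to 26.6%) and 5.58% (4.86 to 6.37%). There were 197 genes with a peak in both knockdown lists and none in the control, TAF15, HNRNPA2B1, PLEKHA4 and CSF1 among them.

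Peaks concentrated towards the 3′ end of coding genes in every list. The last decile of the gene body held 36.8% (35.6 to 37.9%) of regular control peaks, 28.9% (26.8 to 31.2%) of shTRA2A peaks and 32.1% (30.5 to 33.7%) of shMETTL3 peaks. The first decile held 6.40% (5.83 to 7.00%), 8.93% (7.61 to 10.4%) and 8.22% (7.33 to 9.18%). shTRA2A peaks that were not on a control peak were in the last decile in 25.3% (22.6 to 28.1%) of cases and in the first in 11.1% (9.21 to 13.2%). Those on a control peak were there in 34.1% (30.6 to 37.7%) and 5.87% (4.25 to 7.88%). For shMETTL3 the last decile held 30.6% (28.6 to 32.6%) and 34.4% (31.9 to 37.0%), and the first 10.2% (8.94 to 11.6%) and 5.20% (4.09 to 6.51%). Regular control peaks found in shTRA2A were in the last decile in 34.1% (30.3 to 38.1%) of cases, against 37.0% (35.8 to 38.2%) of those not found. For shMETTL3 these shares were 36.3% (33.5 to 39.1%) and 36.9% (35.6 to 38.1%), so found and not found control peaks had overlapping intervals there. The 6 EGFR control peaks lay in the last decile. Exons and untranslated regions were not told apart, as gene bodies alone were used.

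**Figure D3:**
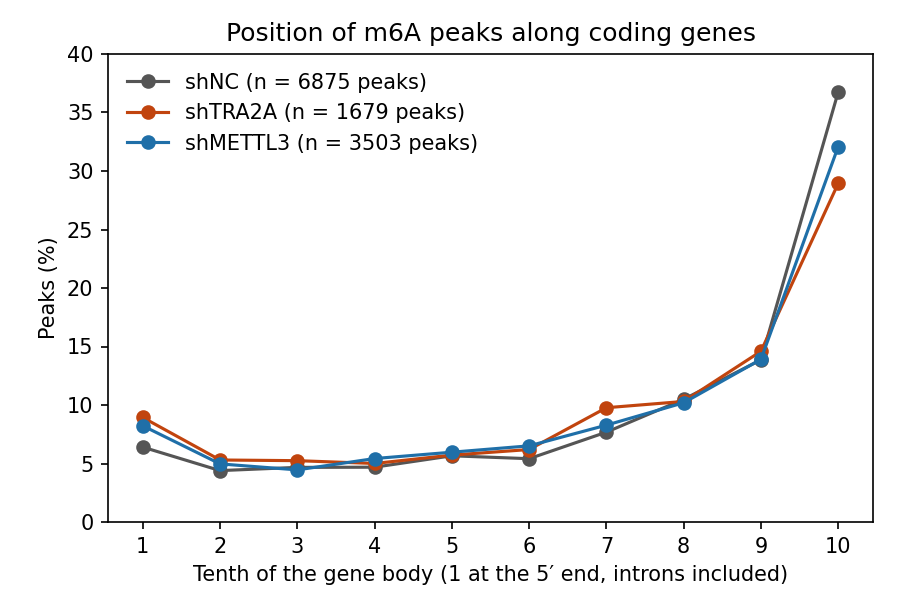
Share of regular m6A peaks, in percent, by decile of the body of their coding gene, introns included, from the 5′ end (1) to the 3′ end (10), for the shNC (6875 peaks), shTRA2A (1679) and shMETTL3 (3503) lists. The last decile holds 36.8%, 28.9% and 32.1% of peaks and the first 6.40%, 8.93% and 8.22%.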

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

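The settings limited to regular peaks, to an shMETTL3 list as long as the shTRA2A list and to all peaks along the gene body were chosen after seeing the data. So were the gene at the middle base and the leaving out of peaks that touch several coding genes. The best control peaks, as many as in the knockdown list, had been planned. No paired analysis was possible because each condition had 1 library pair, and read depth, which limits how many peaks a list can hold, is not given in the sources used here. The DRACH motif and transcript region alternatives and the same-strand gene assignment were not run, as they need a genome, exons and gene strands. Over all control peaks, all control peak genes and all listed genes, the shMETTL3 share exceeded the shTRA2A share under every setting, but single gene lists went both ways. The shMETTL3 list is the longer, at 5433 against 2736 peaks, which alone can give a larger share. Cut to the length of the shTRA2A list it held 11.4% of control peaks against 9.58%, but with its best peaks set against all shTRA2A peaks. Requiring no strand, using the middle base, and leaving out peaks that touch several genes kept the shares within their intervals. Whole spans changed nothing, since nearly all peaks are single blocks.

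Requiring 50% of the shorter peak to be shared gave 17.1% of control peaks found in shMETTL3 and 78.6% absent from both lists. Midpoints within 100 nt gave 7.20% for shTRA2A and 14.5% for shMETTL3, merged peaks 10.7% and 19.6%, and the best control peaks, as many as in the knockdown list, 22.1% and 26.7%. The better-scoring 50% of each list gave 12.04% and 19.0% of peaks, 24.8% and 41.1% of genes, and 26.7% of listed genes for shTRA2A. The same score threshold left 4603, 167 and 994 peaks in shNC, shTRA2A and shMETTL3, though scores of different lists may not share a scale. Genes in place of peaks gave 44.4% absent from both. Ranking by width gave 3.37% and 16.0% in the lowest and highest quintiles for shTRA2A and 6.73% and 25.3% for shMETTL3. The overlap rule for listed genes gave 17.0% and 26.1%. The cause was not tested for the other shifts.

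Regular peaks alone numbered 1822 in shTRA2A. They gave 8.22% and 16.4% of peaks, 23.4% and 41.3% of genes and 25.6% and 41.4% of listed genes found in shTRA2A and shMETTL3, 79.7% absent from both, and 24.1% in the highest quintile for shTRA2A. An shMETTL3 list as long as the shTRA2A list held 11.4%. All peaks gave 33.5%, 23.4% and 26.7% in the last decile of the gene body. Of 34 gene list counts, 14 stayed within 1.5 times under the overlap rule, 13 in the better-scoring 50% and 27 with regular peaks. The overlap rule is stricter, and the better-scoring 50% and regular peaks also leave fewer control peaks. Lower counts therefore come in part from the settings themselves. As shares of listed genes, the better-scoring 50% gave 26.7% and 43.4%, against 32.5% and 46.2% in the main setting. What else moved the counts was not tested.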

Other observations

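The comparison of on-control shares with detection power was set up only after the result was seen, as were the checks by peak width and by strand, including that of spliced peaks with signal on both strands. Among genes with the most peaks in a list, MACF1, a microtubule-actin linker, had 19 control, 8 shTRA2A and 7 shMETTL3 peaks, and GOLGB1, a Golgi tether, 16, 1 and 3. ASPM, a spindle protein, had 6, 0 and 8, and PRRC2C, a stress granule protein, 16, 6 and 10. CALD1, the actin-binding caldesmon, had 3, 7 and 2, and MEIS2, a homeobox transcription factor, 6, 8 and 7.

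Some genes of the fixed lists had knockdown peaks alone, as had 35.1% of all shTRA2A and 39.9% of all shMETTL3 peak genes with respect to the control. ITGA5, the fibronectin receptor subunit, had 3 shTRA2A and 2 shMETTL3 peaks and no control peak. NEAT1, the paraspeckle RNA, had 3 shMETTL3 peaks, the best with a score of 32.8. ERBB2, a receptor of the EGFR family, had 2 shMETTL3 peaks, and TNC, the matrix protein tenascin, had 1.

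The knockdown lists were shorter than the control list, and lower detection power could be the whole cause. The highest share of knockdown peaks on control peaks was 33.8%, while 60.4% and 42.9% in the top deciles of shTRA2A and shMETTL3 were on one, and 64.9% and 60.1% of knockdown peak genes had a control peak. No replicate list shows what share equal power would give. Lower power and loss of m6A in either knockdown therefore both stay open.

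Peaks whose width is not a multiple of 25 nt held a regular peak of the opposite strand inside their span more often than windows beside them, by ratios of 4.04 (2.9996 to 5.77) in shNC, 5.71 (2.91 to 15.0) in shTRA2A and 5.85 (3.50 to 11.4) in shMETTL3. For regular peaks of the same strand the ratios were 0.0355, 0.0606 and 0.0227. A peak caller that joins overlapping peaks of a strand would fix such low ratios in advance. They are therefore no contrast to those of the opposite strand. A regular peak of the opposite strand lay inside 5.09%, 2.24% and 2.36% of the spans in shNC, shTRA2A and shMETTL3, so the ratios concern few spans. In shMETTL3, near-equal pairs of opposite strands were within the range of shuffled scores (22 against at most 32). There the ratio of 5.85 argues against spliced peaks of 1 transcript with no other signal inside as the account of every span. For spans without such a peak, most of the class, that account stays open. In shNC and shTRA2A near-equal pairs of opposite strands were in excess, so spliced peaks with signal on both strands could give the ratios there. That and stretches across introns that take in other transcripts stay open, and no biological explanation was tested.

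None of the 8 control peaks over IFIT1, IFIT2 and IFIT5 shared a base with an shTRA2A peak, and 4.61% of score-matched random sets had as few. The sets were not matched on peak width, so that value may be too low. By midpoints within 100 nt an IFIT1 control peak would count as found in shTRA2A, and the IFIT5 control peak would no longer count as found in shMETTL3. The difference between the knockdown lists over the IFIT control peaks therefore depends on the rule. Random sets by the midpoint rule are not given. Drawn by gene, 8.22% of sets had none, so whether the IFIT genes could differ from other genes with strong control peaks stays open. Lower IFIT transcript levels in shTRA2A cells could give the same picture, and the number of input libraries with gene counts used here was 0.

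Of the 100 best control peaks, 21 were 100 nt or narrower, and 4 of these were found in each knockdown list, against 48 and 56 of the 79 wider ones. Strand was checked for regular peaks whose gene had at least 3 other peaks, at least 75% of them on 1 strand. Of 19 such control peaks of 100 nt or narrower in the best 5%, 4 were on the opposite strand (DNMBP, EP300, NFYA and WTAP). That is 21.1% (6.05 to 45.6%), against 2.95% of 2099 other such narrow control peaks. In the best 5% of shTRA2A it was 3 of 9 (ITGA5, SHROOM3 and ZNF451) and in that of shMETTL3 1 of 65 (ADGRL1). Peaks of opposite strands at the same place numbered 165 pairs in shNC, with scores within 10% in 125 pairs against 24.8 on average for shuffled scores. The values were 36, 34 and 19.6 in shTRA2A and 82, 22 and 18.5 in shMETTL3. Both peaks of such a pair count in the peak numbers of a list or gene, as may be the case in XAF1, whose control peaks were 6 on the plus and 5 on the minus strand. Every overlap share needs the same strand, and with strand ignored 9.95% and 18.6% of control peaks were found in shTRA2A and shMETTL3. All IFIT1, IFIT2, IFIT3 and IFIT5 peaks were on the plus strand.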
